A study of Rattus norvegicus with 8 samples.

How the data were processed

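Gene expression was measured in retinal cells of newborn Lister hooded rats. Per the labels' protocols, retinas taken on postnatal day 0 were electroporated in vitro with a control or a Klf4 plasmid, using square pulses of 25 V and 50 ms. The explants were cultured for 39 hours and dissociated, and GFP-positive cells, those that had taken up plasmid, were isolated by fluorescence-activated sorting before RNA extraction. There were 4 control and 4 Klf4 arrays, numbered 2 to 5 in each group. The labels do not say whether they came from separate animals or electroporations, so p-values measure the spread between these samples, which may be technical.

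Per the file headers, RNA was labelled with Cy3 and hybridised to Agilent single-colour arrays on 1 slide, and spot intensities were extracted with Feature Extraction 10.7.3.1. The deposited intensity values are background-subtracted and detrended by that software and are not scaled between arrays. The deposited flags, unit other, are those of the same software: control type, well above background, saturated and outlier spot. The authors also deposited log2 values, 1 table with 45735 rows, by a method not given in the sources used here. Each column of that table had a median of 7.54, its deciles differed by at most 0.000787 between columns, and it correlated best with its own array (r across probes 0.994 to 1.00). Its scale is therefore log2 with equal quantiles and no centring of genes, and its direction is that of the signals.

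Each array held 62976 spots, of which 58717 were gene spots for 45598 gene probes. The 75th percentile of the gene signals ranged from 2399 (control replicate 5) to 5370 (control replicate 3), and the share of gene spots well above background from 72.1% (Klf4 replicate 4) to 86.5% (Klf4 replicate 2). No spot was saturated on any array, and 324 to 421 outlier spots per array were left out. The number of arrays limits the precision. The headers place both arrays numbered 5 in a second scan and the other 6 in the first. Both arrays numbered 4 were outside the scanner software's quality limits. By their positions on the slide, all controls lay in columns 1 and 3 and all Klf4 arrays in columns 2 and 4. A difference between these columns cannot be told apart from 1 between the groups.

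Control spots and outlier spots were left out, log2 signals of the spots of a probe were averaged, and each array's 75th percentile was subtracted. A probe was kept where it was well above background on at least 3 of the 4 arrays of at least 1 group, and a gene was represented by its kept probe with the highest mean. Probes were named by matching their accessions, without versions, to a RefSeq gene table of assembly GRCr8. Of the 45598 gene probes, 21109 had 1 symbol, 0 had several and 24489 had none (16581 distinct symbols). Probes with no symbol stayed in the tests under the file's own name and are given here only as counts. No coordinates are given, because the file headers name another build, rn4. Kept probes of the same gene were called in disagreement where signs differed or log2 fold changes lay more than 1 apart, as they did in 5 of the 20 named genes with over 1 kept probe.

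Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with no covariates, and a Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold. All fold changes are Klf4 minus control on the log2 scale, with the standard error (SE) of the fit. A gene not well above background on any array of a group has only a bound there. Its fold is written as at least N-fold, from the mean of the brighter group less the mean, over the dimmer group's arrays, of the higher of the lowest signal well above background and the probe's own signal. The bound holds for this processing, and each gene so written had a smaller fold change in some of the alternatives given below. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 28 lists, with camera at an estimated correlation and fry beside it. Genes with a missing value on any array were left out of these list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

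The lists, fixed from general knowledge before the data were examined, were retinal ganglion cell, photoreceptor, bipolar cell, amacrine and horizontal cell, progenitor and Muller glia, neurogenic, S phase, G2 and M phase, cell cycle inhibitors, KLF family without Klf4, epithelial, pluripotency, Wnt pathway, p53 targets, interferon response, immediate early and stress, axon guidance, synapse and mature neuron, actin and smooth muscle, cholesterol synthesis, glycolysis, microglia, endothelium, pericyte and fibroblast, astrocyte, pigment epithelium, lens, and red blood cell. The tests and the rule for named genes were fixed at the same time. That rule names Klf4. It names the 15 largest rises and 15 largest falls past the threshold with no overlap between groups, leaving out names that are only an accession, a clone or a numbered locus. In each list it names up to 4 members past the threshold, or the 2 with the smallest p where none passed. Whatever their result, it names Atoh7, Pou4f1, Pou4f2, Isl1, Ccnd1, Cdkn1a, Cdkn1b, Cdkn1c, Crx, Otx2, Nrl, Hes1, Hes5, Neurog2, Gfap and Mki67. Pou4f1 and Neurog2 were not analysed here, since no probe was matched to them by accession, and 2 genes that the rule names are not reported here.

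The gene fit was tested on simulated data of 29765 genes with 200 changed, 4 arrays against 4. It recovered 41.2% of changes of log2 size 1, 90.9% of size 2 and 100% of size 4, with 10 false calls (6.10% of calls). In simulated lists, each of the 3 list tests called 20 of 20 shifted lists and 0 of 20 unshifted ones. The simulated genes varied independently, while the estimated correlation between genes was 0.749 in the S phase list. The simulation therefore does not test the list calls at such correlations.

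Alternatives were quantile normalization, the array median in place of the 75th percentile, no filter on dim probes, well above background on all 8 arrays, outlier spots kept, the mean over a gene's probes, the authors' values, an intensity trend in eBayes, array weights, the replicate number or the slide row as a block, a minimum log2 fold change of 1, other list tests, and leaving out each array in turn. Added after the data were seen were the scan as a block, the first scan alone, leaving out both arrays numbered 4, and normexp background correction (offset 50) on the median spot signal in place of the planned mean signal, which was not used here.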

Results

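The transcriptome of GFP-positive cells sorted from newborn rat retinal explants was measured 39 hours after electroporation with a control plasmid (4 arrays) or a plasmid for Klf4, a zinc-finger transcription factor (4 arrays). The design asks how overexpression of Klf4 changes gene expression in the transfected retinal cells. On the first principal component, which held 36.3% of the variance, the controls lay between -57.5 and -34.4 and the Klf4 arrays between 24.8 and 83.0. After the filter on dim probes, 30009 genes and unnamed features were tested, 13602 of them with a gene symbol.

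The Klf4 probe read a normalised log2 signal of -3.27 ± 0.62 in the controls and -3.0 ± 0.86 in the Klf4 samples (SD, n = 4 each). The log2 difference of 0.27 was smaller than the spread between replicates (SE 0.46, limma adjusted p = 0.916) and turned to -0.15 without Klf4 replicate 3. In both groups replicate 3 was the highest, at -2.45 and -1.74. Where this probe lies relative to the plasmid insert is not given in the sources used here, so it does not check the labels.

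Gene expression changed mainly upwards. Of 1099 genes and features past the threshold, 960 were higher with Klf4 (619 with a symbol) and 139 lower (86 with a symbol), a share of 87.4% higher. The rises were also larger: 198 were at least 8-fold, and 0 of the limma falls were, against 46 falls of at least 2-fold. These counts use the measured signals and not the bounds, though 79 of the higher genes were not well above background on any control array. Anxa1 rose most, by 9.71 on the log2 scale (SE 0.93, adjusted p = 0.000709). It encodes annexin A1, a calcium-dependent phospholipid-binding protein, and went from -5.51 ± 2.14 in the controls to 4.21 ± 0.45 with Klf4 (SD, n = 4 each). Its relative Anxa8 rose by 9.11, the epithelial membrane protein gene Emp1 by 8.34, and Tnfsf9, a ligand of the tumour necrosis factor family, by 7.78. These 4 were well above background on 1 of the 4 control arrays each, so their folds rest on dim control signals; Anxa1 was highest among the controls on replicate 3, at -2.30. Among the other named rises were the transcription factors Spib (6.96) and Tbx1 (at least 18.2-fold), the matrix genes Ccn3 (at least 17.5-fold), Tgfbi (5.82) and Col11a2 (5.65, and 2.93 with its other probe), and Sertm1 (7.42), Aspg (7.05), Alkal2 (6.23), Tppp3 (6.17) and Gprc5a (5.56). Spib, Sertm1 and Gprc5a were well above background on 1 control array each too, and Aspg and Tgfbi on 2. The lowest values over the alternatives were 4.11 for Spib, 5.13 for Sertm1, 2.34 for Gprc5a, 7.51 for Anxa1, 6.30 for Anxa8, 5.37 for Emp1 and 5.44 for Tnfsf9. For the other named rises they were 2.44 for Tbx1, 2.43 for Ccn3, 4.09 for Tgfbi, 4.29 for Col11a2, 4.52 for Aspg, 4.68 for Alkal2 and 5.71 for Tppp3. Those of Tbx1 and Ccn3 lay below their bounds, which are 4.18 and 4.13 on the log2 scale. All 14 kept their call in each alternative that tested them, with adjusted p up to 0.0461 (Gprc5a).

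**Figure D1:**
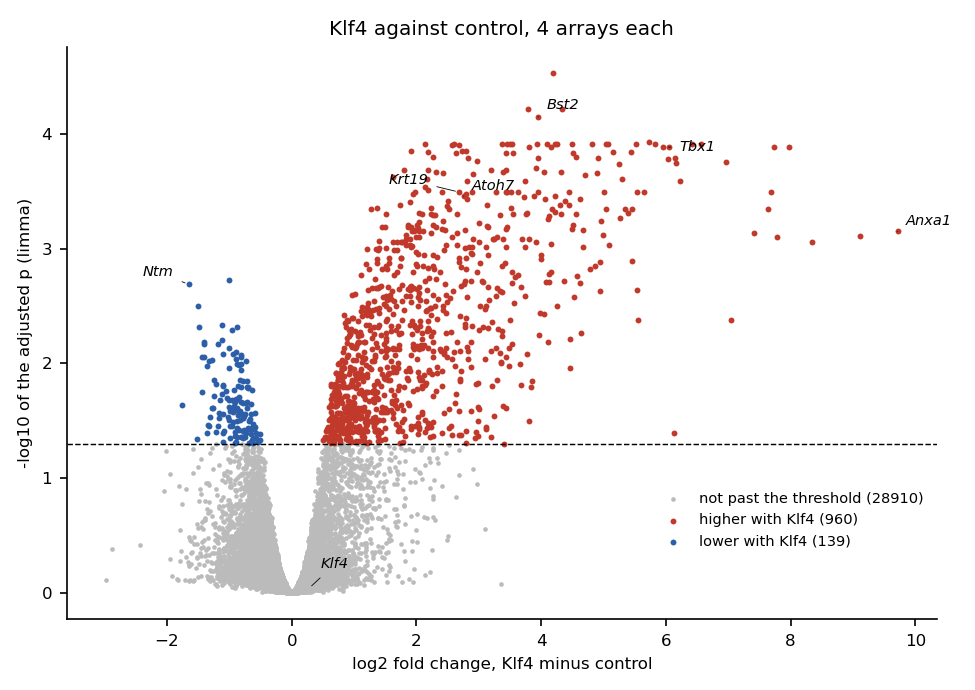
Each point is a gene or feature, with its log2 fold change (Klf4 minus control, 4 arrays each) against -log10 of its limma adjusted p; points above the dashed line, an adjusted p of 0.05, are past the threshold. The 960 higher genes reach 9.71 (Anxa1), while the 139 lower genes reach -1.76, and Klf4 itself lies near 0 at 0.27.

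The falls were fewer and smaller. Ntm, which encodes the neural adhesion molecule neurotrimin, fell by 1.65 (SE 0.19, adjusted p = 0.00206), from -0.03 ± 0.23 to -1.68 ± 0.31 (SD, n = 4 each). Cacna2d4, a calcium channel subunit of photoreceptors, fell by 1.5, Ppp1r17 by 1.49, Birc7 by 1.41, the adrenergic receptor gene Adra1b by 1.41 and Sphkap by 1.35. These 6 kept their call with any single array left out, but Cacna2d4 (adjusted p = 0.109) and Birc7 (0.121) lost it with normexp and Sphkap in the first scan alone (0.0532). The other 9 named falls were Ggta1 (-1.76), Plppr4 (-1.52), Col14a1 (-1.44), the tachykinin gene Tac1 (-1.34), Stk32a (-1.32), Ptprn (-1.28), the cone channel gene Cngb3 (-1.27), the galanin gene Gal (-1.25) and the synaptic gene Cplx3 (-1.24). Each of the 9 lost its call without control replicate 2, with adjusted p from 0.0561 (Gal) to 0.120 (Plppr4), and also without 1 or more of the other arrays, at most 0.136 (Plppr4 without control replicate 3). All 9 also lost it in the first scan alone, from 0.0535 (Gal) to 0.193 (Tac1), and Plppr4, Tac1, Stk32a and Ptprn in further alternatives, up to 0.240 (Stk32a with normexp). With the replicate number as a block, Ggta1, Tac1, Stk32a, Cngb3 and Cplx3 lost their calls too. In the controls all 15 were well above background on 4 arrays, while with Klf4 Birc7 was so on 1 array, Plppr4 and Stk32a on 2, and Ggta1, Cacna2d4 and Col14a1 on 3.

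The count of lower genes moved by over 1.5 times without control replicate 2 (32), 3 (41) or 4 (50), or without Klf4 replicate 2 (38), 3 (68), 4 (406) or 5 (57), and that of higher genes without Klf4 replicate 2 (604). With array weights 1845 genes were higher and 1268 lower, a share of 59.3% higher. The arrays came from 2 scans: with the scan as a block 1147 genes were higher and 254 lower, and the first scan alone gave 632 and 47. In the first scan alone, with fewer arrays, 27 of the 99 named genes lost their call; the second scan held 1 array per group and gives no test.

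Genes that mark retinal ganglion cells shifted up as a list (camera adjusted p = 0.00714), a call that was lost with an estimated correlation (adjusted p = 0.230). Of 28 measured members 7 were higher, 1 was lower and 20 did not pass (9 and 1 adjusted over the list alone), with a median of 0.05 and a mean of 0.46. Stmn2, which regulates microtubules in growing axons, rose by 3.38 (SE 0.41, adjusted p = 0.00237). Atoh7, the transcription factor needed for the formation of ganglion cells, rose by 2.76 (SE 0.23, adjusted p = 0.000350), from -1.31 ± 0.34 to 1.44 ± 0.33 (SD, n = 4 each). Nefm, a neurofilament subunit, rose by 1.89, and Tubb3, neuronal tubulin, by 1.86. Gal was the member that fell. The ganglion cell transcription factors Pou4f2 (-0.25, adjusted p = 0.648, and 0.21 with its other probe) and Isl1 (0.12, adjusted p = 0.984) did not pass. With array weights the list's adjusted p was 0.0763 (0.00240 to 0.230 over the alternatives). It kept its call with the scan as a block (adjusted p = 0.0130) and in the first scan alone (0.0182), and the mean change was 0.36 in the first scan and 0.74 in the second.

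Photoreceptor genes shifted down as a list (camera adjusted p = 0.000189), a call that was lost with an estimated correlation (adjusted p = 0.514) and with fry (adjusted p = 0.188). Of 36 measured members 3 were lower, 0 higher and 33 did not pass (5 lower adjusted over the list alone), and 32 lay below 0, with a median and a mean of -0.42. Rbp3, the retinoid-binding protein of the photoreceptor matrix, fell by 1.10 (SE 0.19, adjusted p = 0.0154), Crx, the homeobox factor of photoreceptor differentiation, by 0.84 (SE 0.18, adjusted p = 0.0379), and the nuclear receptor gene Rxrg by 0.69 (SE 0.16, adjusted p = 0.0497). The rod factor Nrl (-0.99, adjusted p = 0.0876) and Otx2 (-0.44, adjusted p = 0.524) did not pass. Nrl did with the scan as a block (0.0173) and with array weights (0.0206), and Otx2 without Klf4 replicate 4 (0.0374) and with array weights (0.00814). With the scan as a block the list's adjusted p was 1.94e-05 and in the first scan alone 0.00078 (1.34e-07 to 0.514 over the alternatives), and the mean change was -0.38 in the first scan and -0.53 in the second. Rbp3 lost its call without control replicate 2, 3 or 4 (adjusted p 0.0559 to 0.0623), Crx without any control or Klf4 replicate 2 or 3 (0.0564 to 0.132), and Rxrg without any array but Klf4 replicate 4 (0.0841 to 0.173). Further losses were those of Rbp3 without both arrays numbered 4 (0.0729), of Crx and Rxrg with no filter on dim probes (0.0737 and 0.0975), the slide row as a block (0.0604 and 0.0747) and the first scan alone (0.0749 and 0.178), of Crx without both arrays numbered 4 (0.105) and of Rxrg with the array median (0.153). Crx and Rxrg also lost their calls with the replicate number as a block.

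Among the other retinal neuron lists, bipolar cell genes shifted down, with 1 of 16 lower, the homeobox gene Lhx4 (-0.91, SE 0.17, adjusted p = 0.0217; 1 adjusted over the list alone). The list's camera adjusted p was 0.0142, with adjusted p = 0.230 with an estimated correlation and 0.0775 with no filter on dim probes (0.00798 to 0.230 over the alternatives). In the amacrine and horizontal cell list, 2 of 20 rose, Tfap2c by 0.74 and Ptf1a by 0.68 (2 adjusted over the list alone). That list did not shift (adjusted p = 0.946), and its median of -0.09 and mean of -0.07 had the opposite sign to its test. Of 19 neurogenic genes Atoh7 alone rose (1 adjusted over the list alone), and the list did not shift (adjusted p = 0.562, median -0.23, mean -0.02). Without Klf4 replicate 4 the neurogenic list passed as lower (adjusted p = 0.0415, range over alternatives 0.0415 to 0.961). Of 28 synapse and mature neuron genes Rbfox3 rose, by 2.13 (1 adjusted over the list alone), a call lost in the first scan alone (adjusted p = 0.104), with no shift of the list (adjusted p = 0.946). Its median was -0.23 and its mean 0.02, and its direction, down, turned up with quantile normalization. Of 25 axon guidance genes 0 passed with limma, 5 had an unadjusted p under 0.05, and 1 was higher and 2 lower adjusted over the list alone. That list did not shift (adjusted p = 0.624, median -0.11), with Sema3a at -2.02 (adjusted p = 0.0575) and Epha7 at -0.52 (adjusted p = 0.0565). Leaving out 1 array ended the calls of Lhx4 (any but Klf4 replicate 4, adjusted p 0.0525 to 0.0861), Ptf1a (any but control replicate 5, 0.0589 to 0.166) and Tfap2c (control replicate 2 or 3, 0.0585 and 0.0605), and put Sema3a past the threshold without Klf4 replicate 3 (0.00564) and Epha7 without Klf4 replicate 4 (0.0478). The first scan alone also ended the calls of Lhx4 (0.128), Tfap2c (0.0559) and Ptf1a (0.0907), the array median those of Lhx4 (0.0620) and Ptf1a (0.109), and Ptf1a lost its call with no filter on dim probes (0.0945) and without both arrays numbered 4 (0.112). The replicate number as a block ended the call of Lhx4 too. In all, Sema3a passed in 4 alternatives and Epha7 in 6.

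**Figure D2:**
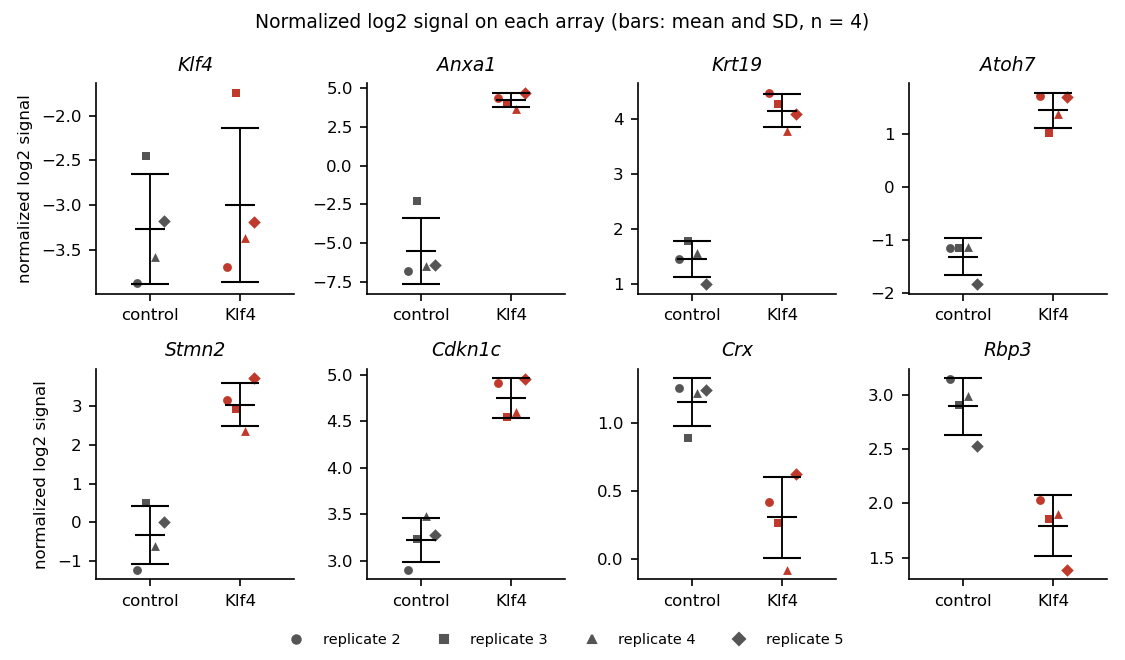
Normalised log2 signal (log2 units relative to each array's 75th percentile) of 8 genes on each of the 4 control and 4 Klf4 arrays, with marker shapes for the replicates and bars for the mean and SD. Klf4 overlaps between groups, Anxa1, Krt19, Atoh7, Stmn2 and Cdkn1c lie higher on all 4 Klf4 arrays, and Crx and Rbp3 lie lower on all 4.

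Progenitor and Muller glia genes did not shift as a list (adjusted p = 0.211, median 0.01, mean 0.06). Of 34 members Vim, the intermediate filament vimentin, rose, by 1.14 (SE 0.19, adjusted p = 0.0129; 2 higher adjusted over the list alone). The Notch effectors Hes1 (0.45, adjusted p = 0.367) and Hes5 (-0.31, adjusted p = 0.779) and the cyclin gene Ccnd1 (0.17, adjusted p = 0.884) did not pass, though Hes1 did with array weights (0.0110). The list was past the threshold in the first scan alone (adjusted p = 0.0490, mean change 0.10) and with array weights (0.0122), but not with the scan as a block (0.238; 0.0122 to 0.554 over the alternatives), and in the second scan its mean change was -0.06. Vim lost its call without control replicate 2 (0.0538) or 4 (0.0526) and in the first scan alone (0.0914).

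Cell cycle genes lay lower with Klf4 as lists, in a shift that leaving out single arrays ended. The camera adjusted p were 0.00678 for S phase and 0.00853 for G2 and M phase, the adjusted p with an estimated correlation was 0.758 for both, and fry gave 0.493 for both. With limma 0 of 35 S phase and 0 of 46 G2 and M phase members passed (0 and 0 adjusted over the list alone), and 0 and 1 had an unadjusted p under 0.05. Below 0 lay 32 and 43 of them, with medians of -0.32 and -0.36. The mean of the S phase list on control replicate 5 was 0.66, against -0.31 to -0.07 on the other controls, and on Klf4 replicate 5, of the same scan, 0.02, against -0.66 to -0.18 on the other Klf4 arrays. Without control replicate 5 the adjusted p were 0.879 and 0.893, without Klf4 replicate 2 they were 0.240 and 0.391, and without Klf4 replicate 4 the G2 and M phase list had 0.125. The adjusted p were 0.000371 and 0.00580 with the scan as a block and 0.0801 and 0.423 in the first scan alone, with mean changes of -0.18 and -0.19 in the first scan and -0.64 and -0.68 in the second. With array weights the S phase list had 0.247 and the G2 and M phase list turned up, at 0.553 (5.02e-05 to 0.879 and 2.95e-05 to 0.893 over the alternatives). Mki67 (-0.32, adjusted p = 0.824), Gins2 (-0.60), Cdca7 (-0.58), Tmpo (-0.35) and Cbx5 (-0.27) did not pass.

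Inhibitors of the cell cycle shifted up as a list, with 3 of 15 higher (4 adjusted over the list alone). Of the members 8 lay above 0 and 7 below, with a median of 0.05 and a mean of 0.24, so they did not rise together. The camera adjusted p was 0.0234, with adjusted p = 0.270 with an estimated correlation. Cdkn1c, which encodes p57, rose by 1.53 (SE 0.17, adjusted p = 0.00149), Cdkn1a, which encodes p21, by 1.51 (SE 0.25, adjusted p = 0.0132) and Tob1 by 0.90, while Cdkn1b was at -0.11 (adjusted p = 0.818). The list lost its call in 9 of 25 alternatives (adjusted p 0.00848 to 0.270 over all 25), among them quantile normalization (0.0524), the mean over probes (0.0785), the authors' values (0.0516), array weights (0.102), leaving out both arrays numbered 4 (0.104), control replicate 2 (0.0518) or Klf4 replicate 4 (0.114). Cdkn1a lost its call without Klf4 replicate 2 (adjusted p = 0.0547), with the mean over probes (0.0732) and in the first scan alone (0.0930). Among p53 targets 5 of 24 were higher and 1 lower (6 and 2 adjusted over the list alone), with a median of 0.12. The rises were the death receptor gene Fas (at least 1.94-fold), Perp (2.78), Cdkn1a, and Phlda3 and Epha2, which the naming rule leaves out and which were chosen after their values were seen. The kinase gene Plk2 fell by 0.96. Fas lost its call with normexp (adjusted p = 0.395) and with no filter on dim probes (0.188). That list had a camera adjusted p of 0.00777, an adjusted p of 0.230 with an estimated correlation and 0.0536 without both arrays numbered 4 (0.00200 to 0.230 over the alternatives). Plk2 lost its call without control replicate 2 or 4 or Klf4 replicate 2 or 5 (adjusted p 0.0553 to 0.0832), in the first scan alone (0.0749) and without both arrays numbered 4 (0.0725). The replicate number as a block ended the call of Plk2 too.

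Epithelial genes were among the rises. Of 30 measured members 7 were higher and 0 lower (7 adjusted over the list alone), while 15 lay above and 15 below 0, with a median of 0.03 and a mean of 0.50. The keratin genes Krt19 and Krt15 rose by 2.69 and 2.65 (SE 0.21 and 0.23, adjusted p = 0.000323 and 0.000505). Krt8 rose at least 3.20-fold, and Perp, a desmosomal protein gene that the p53 list holds too, by 2.78. Krt8 was well above background on 3 of the 4 Klf4 arrays and lost its call with normexp (adjusted p = 0.221). The camera adjusted p was 0.00162, with adjusted p = 0.306 with an estimated correlation (0.000323 to 0.306 over the alternatives). In the family of Klf4, 3 of 13 measured members rose (3 adjusted over the list alone) and 11 lay above 0: Klf3 by 2.43 (SE 0.18, adjusted p = 0.000220), Klf10 by 1.97 and Klf16 by 1.48. That list, without Klf4, had a camera adjusted p of 0.00240, and adjusted p = 0.230 with an estimated correlation (0.00133 to 0.230 over the alternatives).

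Immune, stress, contractile and metabolic lists also shifted up, though none of these 5 did with an estimated correlation (adjusted p 0.230 to 0.309). Their medians were 0.33 (interferon response), 0.24 (immediate early and stress), 0.12 (actin and smooth muscle), 0.24 (cholesterol synthesis) and 0.09 (glycolysis). In the actin and smooth muscle list 9 members lay above 0 and 9 below, and in the glycolysis list 11 and 7. Of 19 interferon response genes 5 rose (7 adjusted over the list alone): the antiviral gene Oasl at least 17.6-fold, Bst2, which encodes tetherin, by 3.95 (SE 0.18, adjusted p = 7.17e-05), the immunoproteasome gene Psmb8 by 2.19 and the transcription factor gene Irf1 by 1.94, and Psmb9, chosen after its values were seen, by 1.36. Psmb8 lost its call in the first scan alone (adjusted p = 0.0564). Oasl kept its call in each alternative that tested it, but its lowest value was 2.30, below its bound of 4.14 on the log2 scale. The list's camera adjusted p was 9.79e-06, and adjusted p = 0.230 with an estimated correlation (3.89e-07 to 0.230 over the alternatives). Of 20 immediate early and stress genes 3 rose (5 adjusted over the list alone), Atf3 by 2.71, Zfp36 by 1.74 and Nr4a1 by 1.30 (camera adjusted p = 0.000614, adjusted p = 0.276 with an estimated correlation and 0.0624 with fry; 1.10e-05 to 0.276 over the alternatives). Of 18 actin and smooth muscle genes 3 rose (5 adjusted over the list alone), the tropomyosin gene Tpm2 by 3.44 (1.72 with a further probe), Tagln by 1.75 and Tagln2 by 1.53 (camera adjusted p = 0.00714, and adjusted p = 0.230 with an estimated correlation; 0.00102 to 0.230 over the alternatives). With probes well above background on all 8 arrays, the actin and smooth muscle list (adjusted p = 0.136) and Tpm2 (0.0508) lost their calls. Of 22 cholesterol synthesis genes 2 rose (4 adjusted over the list alone), Dhcr7 by 1.19 and Acat2 by 1.06, and 19 lay above 0 (camera adjusted p = 6.61e-06, adjusted p = 0.276 with an estimated correlation and 0.0553 with fry; 6.32e-08 to 0.276 over the alternatives). Of 18 glycolysis genes 1 rose (2 adjusted over the list alone), the glucose transporter gene Slc2a1, by 1.69 (camera adjusted p = 0.0484, and adjusted p = 0.309 with an estimated correlation). The glycolysis call was lost in 17 of 25 alternatives (adjusted p 0.0135 to 0.309), among them those without control replicate 2 (0.131), 4 (0.0609) or 5 (0.0899) and without Klf4 replicate 2 (0.128), 4 (0.0688) or 5 (0.0672). Calls of single genes that ended without 1 array were those of Nr4a1 (any but control replicate 4 or Klf4 replicate 4, adjusted p 0.0558 to 0.111), Tagln (any but control replicate 3 or Klf4 replicate 4, 0.0517 to 0.0845), Tagln2 (any but control replicate 5 or Klf4 replicate 4, 0.0733 to 0.0928), Dhcr7 (any but Klf4 replicate 4, 0.0507 to 0.122) and Acat2 (any but control replicate 5 or Klf4 replicate 4, 0.0631 to 0.0929). These 5 also lost their calls in the first scan alone (0.0734 for Dhcr7 to 0.132 for Nr4a1). Further losses were those of Nr4a1 and Dhcr7 with no filter on dim probes (0.0604 and 0.0649), Dhcr7 with the slide row as a block (0.0562), Tagln with normexp (0.118), and Acat2 with quantile normalization (0.0511), the authors' values (0.0513) and the mean over probes (0.179). Nr4a1, Tagln and Acat2 also lost their calls with the replicate number as a block.

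Of the other lists, 2 of 21 Wnt pathway genes rose (2 higher and 1 lower adjusted over the list alone), the ligand gene Wnt2b by 3.1 and the repressor gene Tcf7l1 by 1.41. The list did not shift (adjusted p = 0.562), with a median of -0.01 and a mean of 0.12. Of 10 pluripotency genes 0 passed with limma and 0 had an unadjusted p under 0.05 (0 adjusted over the list alone; list adjusted p = 0.740, median 0.01, mean -0.08). The 2 with the smallest p were Dppa3 (-0.55, adjusted p = 0.441) and Tfcp2l1 (-0.24, adjusted p = 0.667), and Dppa3 was past the threshold without Klf4 replicate 4 (adjusted p = 0.0274) and with array weights (0.0118).

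Markers of cells from outside the neural retina, or of its vessels and glia, gave no common direction. Of 6 endothelium genes 2 rose (2 adjusted over the list alone), the receptor gene Tek by 2.38 and Esam at least 3.90-fold, with a camera adjusted p of 0.00776, adjusted p = 0.230 with an estimated correlation and 0.0873 with probes well above background on all 8 arrays (0.000169 to 0.230 over the alternatives). Of the 13 genes of the endothelium list only 6 were measured, and their median was 0.08. Cdh5 (-0.01), Kdr (0.03) and Flt1 (-0.02) did not pass. Esam was well above background on 3 of the 4 Klf4 arrays and lost its call with normexp (adjusted p = 0.0877) and in the first scan alone (0.0837). Of 13 microglia genes 1 rose (1 adjusted over the list alone), C1qb, by 1.04 (list adjusted p = 0.403, median 0.13). Of 7 pericyte and fibroblast genes 2 rose (2 higher and 1 lower adjusted over the list alone), Cspg4 by 1.62 and Col1a1 by 1.36, with no shift (adjusted p = 0.339, and 0.0382 with fry; 0.0382 to 0.988 over the alternatives), a median of -0.05 and a mean of 0.21. Of 8 astrocyte genes S100b rose, by 3.80 (1.49 with its other probe; 1 adjusted over the list alone), and Gfap was at -0.40 (adjusted p = 0.667). The astrocyte list did not shift (adjusted p = 0.928), with a mean of 0.29 but a median of -0.15 and a test that pointed down, and up with normexp. With limma 0 of 3 pigment epithelium, 0 of 10 lens and 0 of 4 red blood cell genes passed, and in each list 1 had an unadjusted p under 0.05. Adjusted over the list alone, 1 pigment epithelium gene was lower. Their list adjusted p were 0.562, 0.170 and 0.147, with medians of 0.08, -0.28 and 0.17, and the pigment epithelium list had a mean of -0.42 and a test that pointed down. In these lists Ttr was at -1.45 (adjusted p = 0.136), Mitf at 0.12 (-0.06 with its other probe), Bfsp2 at -0.68, Crygs at -0.25, Hba-a2 at 0.61 and Ahsp at 0.26. The call of S100b ended without any array but control replicate 3 (adjusted p 0.0528 to 0.109) and that of C1qb without control replicate 2 or 4 or Klf4 replicate 2 or 3 (0.0651 to 0.0826). S100b also lost it in the first scan alone (0.166), with no filter on dim probes (0.0563) and without both arrays numbered 4 (0.103), and C1qb in the last (0.0922). The replicate number as a block ended the call of S100b too. Ttr passed without Klf4 replicate 4 (0.0326) and in 5 alternatives in all, and the lens list was past the threshold as lower without control replicate 5 (0.0463) and in the first scan alone (0.0446; 0.0446 to 0.576 over the alternatives).

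**Figure D3:**
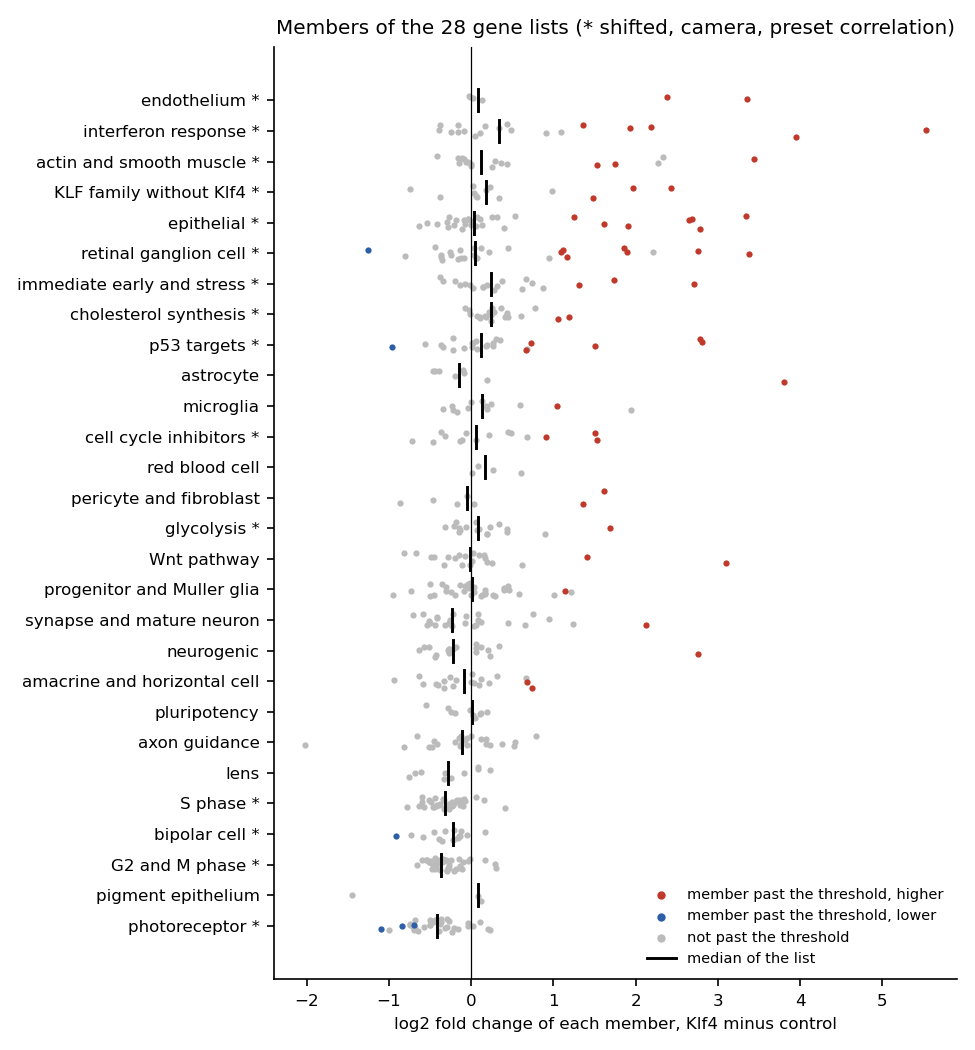
Each point is a measured member of a gene list, placed by its log2 fold change (Klf4 minus control), coloured where it passed the threshold over all genes, with a black bar at the list's median. Asterisks mark the 15 of 28 lists that shifted with camera at a preset correlation; most members of the photoreceptor list lie below 0, while the epithelial list has 7 high members around a median of 0.03.

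Over all 28 lists, camera called 15, of which 11 shifted up and 4 down. With an estimated correlation it called 0, with a smallest adjusted p of 0.230 and 5 lists at an unadjusted p under 0.05. With fry, which asks whether the genes of a list move on balance in 1 direction, 11 lists passed, 10 of them among the 15.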

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

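The count of other splits, the models of control replicate 3 and the slopes of Klf4 replicate 4 were tests chosen beforehand; those of spot noise, of a higher floor, of genes with no response, of epithelial cells, of scaling and of an offset at the floor were chosen after the result was seen.

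Of the 35 splits of the 8 arrays into 4 and 4, the real one called 1099 genes and the highest other called 0 with limma, so 1 split reached the real count. Each other split mixes the groups, which puts the Klf4 differences into its residuals and lowers its count. This count therefore cannot exclude chance. At an unadjusted p under 0.05 the real split had 3577 genes, and 3 of the 34 others had more, up to 4993, so that count alone does not set the real split apart. Each of those 3 put both arrays of the second scan and Klf4 replicate 4 on the same side. A structure of the samples that follows the scan cannot be told apart there from that array. Among splits with 1 array of the second scan on each side, the real one had the most such genes, 3577 against at most 1775. That comparison was not planned. With the scan as a block 1147 genes were higher and 254 lower.

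Single arrays lay far from the other 3 of their group in 17 of 257 groups of values tested, where chance gives about 1 in 20 (14 of 197 gene groups, 7.11%, and 3 of 56 list groups). Of the 17, 10 were on control replicate 5, 4 on control replicate 3, 2 on Klf4 replicate 4 and 1 on control replicate 2. All values are normalised log2 signals or list means of them.

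On control replicate 3, Anxa1 read -2.30 (other controls -6.83 to -6.39), Anxa8 -3.54 (-7.96 to -7.31), Ptprn -2.54 (-3.0 to -2.95) and Crx 0.89 (1.22 to 1.26). On control replicate 2, Adra1b read -0.085 (-0.67 to -0.59). On Klf4 replicate 4, Ggta1 read -5.11 (other Klf4 arrays -3.84 to -3.66) and Hes5 1.42 (2.45 to 2.47).

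On control replicate 5, Atoh7 read -1.83 (other controls -1.15 to -1.14), Tubb3 0.29 (0.75 to 0.84), Perp -3.67 (-3.23 to -3.17), Tfcp2l1 -2.14 (-2.64 to -2.56), Tek -3.07 (-2.48 to -2.44), Ahsp -2.79 (-1.85 to -1.69) and Hes5 2.99 (2.30 to 2.39). Its list means were -0.19 for pluripotency (0.05 to 0.08), 0.21 for p53 targets (-0.09 to -0.04) and -0.82 for microglia (0.21 to 0.33). It is the control of the second scan, and no explanation was tested for it.

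Control replicate 3 held a trace of genes raised with Klf4. Of 72 genes raised at least 8-fold and not well above background on the other 3 controls, 31 were well above background there. The same count gave 7 of 46, 1 of 46 and 0 of 48 for control replicates 2, 4 and 5. Those sets hold no gene well above background on control replicate 3, so the counts are not of the same genes. Fewer gene spots were well above background on control replicates 4 (79.0%) and 5 (75.2%) than on 3 (86.1%). The median log2 level over the other controls was 0.29 on control replicate 3, against -0.87, 0.30 and 0.67 on 2, 4 and 5. An additive share of the Klf4 level left a residual SD 0.769 times that of a fixed fraction of each gene's log2 change (95% bootstrap interval 0.669 to 0.914), or 0.917 with an offset at the floor (0.862 to 0.978). This argues against a response in these cells that is a fixed fraction of each gene's log2 change. A response in only a few of the cells would also give an additive share, so the fit cannot tell it from carry-over. Carry-over from a Klf4 sample is a candidate explanation. The share fitted here, 0.926% (0.663 to 1.19), lay between those fitted on control replicates 4 (0.713%) and 5 (1.56%). With an offset at the floor it was 1.09%, above those of control replicates 4 (0.574%) and 5 (0.629%). The order thus depended on the fit. The size of the share stays open, and so does whether cells, RNA or label were carried over.

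Klf4 replicate 4 stood apart from the other Klf4 arrays, and without it 1221 genes were higher and 406 lower. Spot noise is argued against, since its median CV between replicate spots was 2.80% against 3.07% to 3.46% on the other arrays. The floor of this array was higher, with a median negative-control signal of 12.7 against 3.72 to 6.71 on the others. Among the brightest genes its deviation (MAD) was 0.358 log2 units (0.348 to 0.368) against at most 0.262 on the other Klf4 arrays. This argues against a higher floor as the only cause. Among the dimmest genes the deviation was 0.94 against at most 0.71, so a part of the floor there stays open for Klf4 replicate 4. A weaker response may account for its called genes: the slope of its change on that of the other Klf4 arrays was 0.709 (0.682 to 0.734) against 0.919 to 1.11, and 0.805 against 0.953 to 1.10 over the same 622 genes. It leaves the rest open, since among 6257 genes with no response the deviation was still 0.343 (0.333 to 0.356) against at most 0.257. The ribosomal RNA probes were low on this array too, with Rn18s at -3.21 against 2.11 to 4.79 on the others, and the cause of this was not tested.

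Epithelial genes were among the rises, though the labels name a retina. The 30 measured members of the list had a median log2 fold change of 0.0294 (0.29 at the upper bound), so they did not rise together. Krt5 (-0.20), Krt14 (0.06), Cdh1 (-0.09), Cldn4 (-0.01) and Cldn7 (0.10) did not pass. Evpl (1.91), Elf3 (1.62) and Jup (1.24) rose, as did Krt15, Krt19, Krt8 and Perp. This argues against surface epithelial cells that express the whole list in the Klf4 samples. It cannot decide on cells that express part of it, and the sort for GFP would remove only untransfected cells. Scaling of the arrays is argued against, since 92.5% of the higher genes were called higher again with the array median and 96.7% with quantile normalization. With normexp, a background correction, it was 83.8%. A response of the transfected cells to Klf4 may explain the rises, as a hypothesis.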

How the results depend on the processing

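The scan as a block, the first scan alone, leaving out both arrays numbered 4, and normexp on the median spot signal were tests chosen after the data were seen.

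No gene called in the main comparison was called in the opposite direction in any alternative. The 99 named genes kept direction and call in 2018 of 2248 comparisons, lost the call in 205, gained it in 25 and reversed in 0, and 13 uncalled values changed sign. The gained calls were of Ttr, Epha7, Sema3a, Hba-a2, Dppa3, Bfsp2, Otx2, Nrl and Hes1. The 28 lists kept both in 636 of 700, lost the call in 57, gained it in 6 and reversed in 1, and 24 uncalled ones changed sign. Of the 960 higher genes 804 were called again with normexp, 928 with quantile normalization and 888 with the array median.

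With no filter on dim probes 39506 features were tested, and 70 genes were lower. With a log2 fold change of at least 1, 46 were lower. With the scan as a block 254 were lower, and the cause was not tested. The first scan alone, with fewer arrays, gave 632 higher and 47 lower genes, and adjusted p of 0.0490 for the progenitor and Muller glia list, 0.0801 for S phase and 0.423 for G2 and M phase.

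Array weights gave 1845 higher and 1268 lower genes (59.3% higher, against 87.4%). The adjusted p were then 0.0763 for the retinal ganglion cell list, 0.0122 for progenitor and Muller glia, 0.247 for S phase and 0.553 for G2 and M phase, which turned up. The cause was not tested.

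With an estimated correlation camera called 0 lists, and 5 had an unadjusted p under 0.05. The adjusted p were 0.230 for retinal ganglion cell, 0.514 for photoreceptor and 0.758 for both S phase and G2 and M phase. With fry, which called 11 lists, they were 0.188 for photoreceptor and 0.493 for both cell cycle lists. The cause of these losses was not tested.

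Leaving out 1 array gave 604 (without Klf4 replicate 2) to 1221 (without Klf4 replicate 4) higher genes and 32 (without control replicate 2) to 406 (without Klf4 replicate 4) lower genes. The adjusted p ranged from 0.0415 to 0.961 for the neurogenic list, from 5.02e-05 to 0.879 for S phase and from 2.95e-05 to 0.893 for G2 and M phase, the highest of both cell cycle lists without control replicate 5. Fewer arrays lower the counts, but the cause of the rise without Klf4 replicate 4 was not tested here.

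Correlations of the deviations of arrays with the same number were 0.355, 0.243, 0.0608 and 0.551 for numbers 2 to 5, the best of each array for numbers 2, 3 and 5 but not for 4. This is a hint of shared deviations for 3 of the numbers, and the correlation gave none for number 4. List means were mixed for number 4. In the photoreceptor list control replicate 4 (0.43) and Klf4 replicate 4 (-0.02) were each the highest of their group. In the interferon response list control replicate 4 was the highest (0.21) and Klf4 replicate 4 the lowest (0.71). The labels do not say what a number marks, so pairing stays open. The main fit, fry and the fits with 1 array left out did not treat the arrays as pairs. With a replicate block 842 genes were higher and 101 lower, 13 named genes (Ggta1, Tac1, Stk32a, Cngb3, Cplx3, Crx, Rxrg, Lhx4, Plk2, Nr4a1, Tagln, Acat2 and S100b) were not called and 1 more was. Of the lists 27 of 28 kept their call, with adjusted p of 1.26e-06 for photoreceptor, 8.81e-05 for S phase and 0.000306 for G2 and M phase, and cell cycle inhibitors had 0.0500. The S phase mean was lower on the Klf4 array of each of the 4 numbers. The G2 and M phase mean was lower there for numbers 2, 4 and 5, but for number 3 it was 0.20 on the Klf4 array against -0.08 on the control. With the slide row as a block 883 genes were higher and 118 lower, and Crx, Rxrg, Dhcr7 and the glycolysis list (0.0502) lost their calls.

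Signal over background limits the folds: 79 of the higher genes were not well above background on any control array, and 689 were on all 4.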

Other observations

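These values were chosen after they were seen, and no test was planned for them.

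On Klf4 replicate 4 the ribosomal RNA probes were low: Rn18s read -3.21 (other arrays 2.11 to 4.79), Rn45s 3.96 (7.93 to 8.67) and Rn5-8s -3.67 (2.21 to 4.33), as normalised log2 signals.

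Both arrays numbered 3 were the highest of their group for Chat (control -0.03, Klf4 -0.81), Rgs4 (1.36 and 0.74), Pnoc (0.39 and -0.20) and Dcx (1.13 and 0.21). Arrays numbered 4 came next in both groups: Chat (-2.38 and -3.59), Rgs4 (-0.90 and -2.31), Pnoc (-1.79 and -2.40) and Dcx (-0.76 and -0.90). Cryab was high on control replicate 3 (0.68) and not on Klf4 replicate 3 (-2.90).

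Krt1, outside the epithelial list, rose by 5.52 on the log2 scale (limma adjusted p = 0.000123) and was well above background on 1 control array. The endothelial genes Cdh5 (-0.01), Kdr (0.03) and Flt1 (-0.02) did not pass, beside the rises of Tek and Esam.

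Of 420 gene families with at least 5 measured members, grouped by the stem of the symbol, 0 held more higher genes than chance gives by Fisher's exact test after adjustment. The smallest adjusted p were 0.140 for collagens (6 of 22 higher), 0.146 for annexins (4 of 10) and 0.260 for keratins (6 of 30), against 4.52% of the 10283 background genes.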
